A study of Mus musculus with 25 samples.

How the data were processed

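The series holds bulk RNA sequencing of CD11b+ cells sorted from the spinal cord of C57BL/6 mice at the onset of experimental autoimmune encephalomyelitis (EAE), a model of neuroinflammation. Per the labels, CD45lo cells were taken as microglia and CD45hi cells as infiltrating monocytes and macrophages, here called macrophages. Each cell type was divided by surface MHC II and by DCFDA, a dye that becomes fluorescent on oxidation and reads out reactive oxygen species (ROS), into 4 gates. The MHC II- ROS- gate is the baseline the series names. The 8 groups held 23 libraries, with n = 3 each except microglia MHC II+ ROS- (n = 2), and 2 more libraries came from healthy mice, 1 of microglia and 1 labelled bone marrow-derived macrophage. The table gives 2 of the 3 macrophage MHC II+ ROS+ libraries the same header, so these are called unnumbered-a and unnumbered-b in the order of the table. The labels do not say that replicates came from separate animals, so each p-value measures only the spread between these samples.

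The authors deposited raw counts per gene for 37991 Ensembl genes of mouse genome build mm9. The submitters' processing notes name FastQC, TopHat2 2.0.13, featureCounts of Subread, and edgeR. The gene set, the strand setting and the handling of reads that fit several places are not stated, so counts of close paralogs such as Ly6c1 and Ly6c2 cannot be assigned to one member with certainty. The same table holds the authors' log2 fold changes between pairs of gates, and the authors' false discovery rates (a p-value adjusted by Benjamini-Hochberg, per the file headers). Coordinates are those of the table, and its 25 columns of normalized values were not used. Total counts of the EAE libraries ran from 19479445 to 46522794. Mitochondrial genes took a large part of them, so that nuclear counts ran from 4883612 to 8710038 in the microglia baseline and from 13090365 to 18363726 in microglia MHC II+ ROS+. Over 22 pairs of replicates, differences exceeded counting error (chi-square per degree of freedom 56.1 to 570.2). Mitochondrial share can enter this, and genes with few counts stay unjudged. Intervals and floors below cover counting error only. A gene with 0 counts in a group was set to 3 counts over the group, and its fold is given as "at least". A gene with 1 to 3 counts has a ratio of CPM (counts over the library's total, scaled to a common size over the 23 EAE libraries, or over all 25 beside a healthy library) with a 95% counting interval.

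All 23 EAE libraries were fitted in 1 model with 8 group means by edgeR 4.0.16 (R 4.3.3; TMM scaling, filterByExpr, quasi-likelihood F test), with Benjamini-Hochberg adjustment over the 18502 genes tested and a threshold of 0.05. Every adjusted p of a gene below is from this test unless another is named. Errors of log2 fold changes are standard errors (SE), and errors of CPM are standard deviations (SD). The 12 comparisons were 5 pairs of gates within each cell type, microglia against macrophages over the mean of the 4 gates, and the difference between both cell types in MHC II+ ROS+ against baseline. The model, the comparisons, the gene lists, the rule for naming genes and the alternatives listed first below were chosen before the data were examined. The 33 lists (572 symbols, of which 571 matched the table) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. They covered antigen presentation, oxidants, coagulation, microglial states, cytokines, interferon responses, cell cycle, metabolism, phagocytosis, receptors, tissue dissociation, and markers of 12 cell types a CD11b+ sort could hold. Per comparison the text could name the 8 largest rises and 8 largest falls among called genes whose libraries did not overlap and whose mean reached 10 CPM in the higher group, and up to 4 lowest-p members of each list it speaks of. It could also name 14 fixed genes: H2-Aa, H2-Ab1, H2-Eb1 and Cd74 (a check of the MHC II gate), Tmem119, P2ry12, Ccr2, Ly6c2, Cybb, Hmox1, Ggt5, F10, Il1b and Clec4e. Predicted genes without a proper symbol were counted and not named. Pdgfb stands outside the rule, as the last of a count of 3, and was chosen after its values were seen, as were S100a8, S100a9 and Ngp in groups where they are given only as levels.

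On simulated data of the same dispersion, edgeR recovered 19 of 100 genes changed 4-fold and 73 of 100 changed 16-fold in microglia, with 2 false calls. It recovered 22 and 76 of 100 in macrophages, with 3 false calls, so many true changes of 4-fold stay below the threshold at this spread. The alternatives chosen with the model were RLE size factors, no filter, the Wald test of DESeq2 1.42.0 and each cell type fitted alone. So were the replicate number as a block, each library left out (not in list tests) and, for lists, an estimated correlation and fry. Added after seeing the data were limma voom with library weights, the mitochondrial share as a covariate, mitochondrial genes left out, the 4 libraries with fewest genes left out, a minimum of 10 CPM, genes with long purine or pyrimidine stretches left out, the block with both unnumbered libraries exchanged, and for list tests RLE and no filter. Replicate numbers were treated as pairs only where residual correlations of all numbered pairs exceeded 0.1, which held for microglia MHC II- ROS+ against baseline (0.11 to 0.12) and, with both unnumbered libraries in table order, macrophage MHC II+ ROS+ against MHC II- ROS+ (0.19 to 0.43, but -0.26 to 0.19 when exchanged). Stretches were sought in GENCODE release 21 transcripts of mouse build GRCm38 with Python 3.11.15 and NumPy 2.4.6, matched by gene identifier for 32919 of 37991 genes, and similarity to the mitochondrial genome with BLAST+ 2.17.0. The healthy libraries stayed outside every test. Each was set against the 3 baseline libraries of its cell type, with list medians placed among those of 10000 random lists of matched expression.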

Results

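RNA of spinal cord microglia and macrophages at EAE onset was sequenced by gate, to compare cells by ROS and surface MHC II. Total counts ran from 19479445 to 32716881 in the 6 microglia ROS+ libraries, from 33028420 to 46522794 in the 5 microglia ROS- libraries and from 24235332 to 43222654 in the 12 macrophage libraries. Genes with at least 1 count numbered from 13277 to 20465 per EAE library. The 4 libraries with fewest such genes were microglia MHC II+ ROS- replicate 2 (13277), macrophage MHC II+ ROS- replicate 3 (13525), microglia MHC II+ ROS+ replicate 2 (14106) and microglia baseline replicate 3 (14348). Non-overlap of libraries was the rule for naming largest rises and falls, so it is no evidence. It was not applied to the difference between cell types.

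Microglia and macrophages, averaged over 4 gates, were compared first, to see what the CD45 gate separated. P2ry12, a purinergic receptor of resident microglia, stood at 395 ± 175 CPM in microglia (n = 11) and 17.5 ± 8.57 CPM in macrophages (n = 12), a log2 fold change of 4.54 ± 0.25 (adjusted p = 1.66e-10). Tmem119, a surface protein of microglia, was also higher, by 4.06 ± 0.25 (425 ± 121 against 25.9 ± 10.7 CPM). Ccr2, the receptor through which monocytes follow CCL2, was lower in microglia, at 14.01 ± 17.89 against 361 ± 174 CPM (log2 fold change -5.34 ± 0.51). Ly6c2, a marker of inflammatory monocytes, differed by -4.36 ± 0.44. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, differed by -2.48 ± 0.19 (210.4 ± 130.4 against 979.8 ± 187.9 CPM). The genes of coagulation factor X (F10, -4.07 ± 0.46), interleukin-1β (Il1b, -2.84 ± 0.32) and the receptor Mincle (Clec4e, -3.59 ± 0.44) were lower as well.

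Among the largest rises in microglia were Prox1, a homeobox transcription factor (8.59 ± 0.87), the organic cation transporter gene Slc22a17 (7.54 ± 0.79) and the receptor phosphatase Ptprm (7.20 ± 0.71). The spindle checkpoint kinase Ttk (6.87 ± 0.78), the BMP receptor Bmpr1a (6.83 ± 0.66), Gas6, a ligand of TAM receptors (6.72 ± 0.56), and the matrix protein gene Npnt (6.70 ± 0.54) belonged to them too. Among the largest falls were the adenosine receptor Adora2b (-7.40 ± 0.83) and Il12a, a subunit of interleukin-12 (-6.27 ± 0.50). Dgat2, which makes triglycerides (-5.44 ± 0.72), was another. In all, 4099 of 18502 genes passed, 2065 higher and 2034 lower in microglia, of which 554 were predicted genes without a proper symbol. Of the largest changes and the 14 fixed genes, all 27 that passed did so without each library in turn. The count fell to 1088 with the mitochondrial share as a covariate and to 2378 with a minimum of 10 CPM.

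Of the 33 gene lists, 22 were called between microglia and macrophages, and 8 of these also with an estimated correlation. Homeostatic microglia genes were higher in microglia in 22 of 25 members, with 1 lower (23 and 1 adjusted over the list alone; adjusted p = 3.82e-27, and 0.00102 with an estimated correlation). Cx3cr1 (3.82 ± 0.20) was among them. Cell cycle genes were higher in 24 of 25 (24 adjusted over the list alone; 2.57e-20 and 0.00237). Top2a, a topoisomerase of dividing cells, stood at 4.08 ± 0.37 and Mki67 at 2.1 ± 0.21. Monocyte markers were lower in 15 of 16 (16 adjusted over the list alone; 3.15e-20 and 0.00688). Type I interferon response genes were lower in 22 of 25 (22 adjusted over the list alone; 5.24e-13 and 0.0121). Among them were the RNA sensor Ifih1 (-2.23 ± 0.22) and Irf7 (-2.57 ± 0.32). Glycolysis genes were lower in 17 of 20 and higher in 1 (17 and 1 adjusted over the list alone; 1.28e-11 and 0.0153). Genes of C-type lectin and Toll-like receptors were lower in 13 of 21 and higher in 2 (4.28e-07 and 0.0307). Those of alternative activation were lower in 8 of 16 and higher in 1 (0.000137 and 0.0380), with Arg1 at -3.99 ± 0.50, and those of border-associated macrophages lower in 5 of 10 (0.000229 and 0.0183). Adjusted over the list alone these 3 lists had 14, 8 and 5 lower members. Over all alternatives the adjusted p of the 8 lists ran from 1.57e-33 to 0.0686, the highest being that of border-associated macrophages without genes that hold long stretches.

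The other 14 lists lost their call with an estimated correlation, where their adjusted p lay between 0.0767 and 0.195. Lower in microglia were the lists of NADPH oxidase and other oxidant sources (6 of 15 lower, 1 higher; 0.0120 before and 0.0801 then), antioxidant defence (9 of 22; 0.00134 and 0.124) and coagulation (13 of 23 lower, 4 higher; 0.00175 and 0.0960). So were those of inflammatory cytokines (13 of 26 lower, 4 higher; 0.000229 and 0.195), interferon-gamma response (11 of 20 lower, 1 higher; 1.61e-05 and 0.0801) and lipid handling (8 of 21 lower, 3 higher; 0.0254 and 0.177). T cell markers (12 of 16; 6.52e-06 and 0.0801), MHC class I (7 of 14 lower, 1 higher; 0.00765 and 0.195) and MHC class II (6 of 14 lower, 2 higher; 0.0309 and 0.195) were lower as well. Nos2, the inducible nitric oxide synthase, stood at -4.32 ± 0.59. Higher in microglia were complement (8 of 17 higher, 4 lower, with C1qc at 3.87 ± 0.26; 0.0299 and 0.0960), and the mitochondrially encoded genes (12 of 12; 1.59e-11 and 0.0857), as were neuron (4 of 10; 0.000229 and 0.0767), oligodendrocyte (3 of 8; 0.0323 and 0.0801) and astrocyte markers (1 of 10; 0.0214 and 0.131). In that order, adjusted over the list alone, the first 9 lists had 6, 12, 14, 15, 14, 10, 14, 10 and 6 lower and 1, 0, 5, 4, 1, 3, 0, 1 and 2 higher members. The last 5 had 8, 12, 4, 4 and 1 higher and 4, 0, 0, 0 and 0 lower ones. Their adjusted p over the alternatives ran from 3.97e-14 to 0.320. Leaving out 1 library ended the call of MHC class II (microglia MHC II+ ROS+ replicate 3, 0.0519) and complement (microglia baseline replicate 2, 0.0538). Oligodendrocyte markers missed without 1 of 3 libraries (microglia MHC II- ROS+ replicate 1, 0.0533, microglia baseline replicate 3, 0.0596, and macrophage baseline replicate 2, 0.0553).

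The share of counts on mitochondrial genes differed between ROS gates. The share was 80.5 ± 5.83% in ROS- (n = 5) and 33.2 ± 8.69% in ROS+ microglia (n = 6). In macrophages it was 47.3 ± 12.6% (n = 6) and 22.79 ± 3.101% (n = 6). By group it ran from 21.8 ± 3.87% (macrophage MHC II+ ROS+) to 83.4 ± 5.25% (microglia baseline). In both cell types every ROS- library lay above every ROS+ library (two-sided exact permutation test, p = 0.00216, the smallest possible; adjusted p = 0.00432 over 6 tests). Total counts of microglia were 41450000 ± 5537000 in ROS- and 25460000 ± 5636000 in ROS+ libraries (p = 0.00216, adjusted p = 0.00432, same exact test). Those of macrophages did not pass (p = 0.755, same exact test). Detected genes were fewer in ROS- macrophages (15640 ± 1589 against 18940 ± 1298; p = 0.00649, adjusted p = 0.00974, same exact test). In microglia they did not pass (15190 ± 1591 against 17660 ± 1984; p = 0.0541, adjusted p = 0.0649, same exact test).

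**Figure D1:**
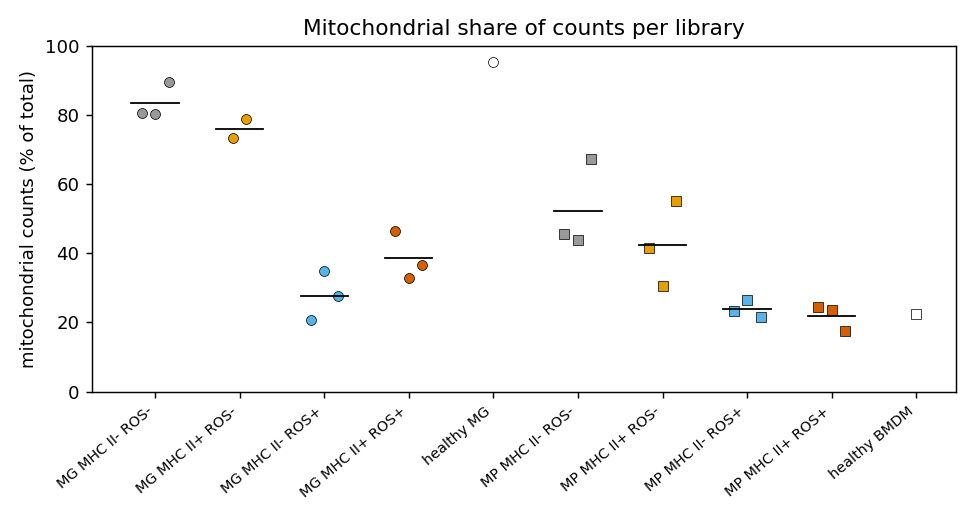
Share of counts on mitochondrial genes (percent) by group, points being libraries and bars group means. ROS- libraries reached from 30.4% upwards in macrophages and from 73.3% upwards in microglia, against at most 26.5% and 46.4% in ROS+ libraries.

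MHC II+ ROS+ were set against MHC II- ROS+ microglia to see what goes with MHC II among ROS+ cells. Beside the gated MHC II genes, 2 chemokine genes that draw T cells were higher in MHC II+ ROS+. Ccl5 stood at 56.5 ± 16.5 CPM against 3.68 ± 1.99 (n = 3 each; log2 fold change 3.94 ± 0.56, adjusted p = 0.00360), and the interferon-gamma target Cxcl9 at 305.0 ± 70.5 against 38.6 ± 15.7 CPM (2.98 ± 0.48, adjusted p = 0.0107). Transcripts of Cxcl9 hold a purine or pyrimidine stretch of 80 bases. As a check of the gate, H2-Eb1 rose by 4.32 ± 0.55, H2-Aa by 4.27 ± 0.51, H2-Ab1 by 3.92 ± 0.60 and Cd74, the invariant chain, by 3.79 ± 0.60. These were the 6 genes called, with 1725 genes at an unadjusted p below 0.05. Cybb stood at 223.2 ± 99.7 against 62.1 ± 9.89 CPM without passing (1.85 ± 0.34, adjusted p = 0.0638). Without MHC II- ROS+ replicate 1 or replicate 3 the count was 2, H2-Eb1 and H2-Aa. Without MHC II- ROS+ replicate 2 it was 10, and without MHC II+ ROS+ replicate 2 the call of Cxcl9 ended. The count was 237 with DESeq2, 60 with limma voom and library weights, 11 with a minimum of 10 CPM and 1 with microglia fitted alone.

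Interferon and antigen presentation genes rose together here. In the type I interferon list 23 of 25 genes were higher (10 adjusted over the list alone, 0 over all genes; adjusted p = 1.76e-10, and 0.0273 with an estimated correlation). Oasl1 stood at 2.23 ± 0.61 and Oas1a at 2.03 ± 0.58. In the interferon-gamma list 17 of 20 were higher (6 adjusted over the list alone, 1 over all genes; 2.67e-09 and 0.0292). The GTPase genes stood higher, Gbp6 at 2.32 ± 0.57 and Gbp2 at 1.28 ± 0.36. All 14 MHC class I genes were higher (8 adjusted over the list alone, 0 over all genes; 6.56e-10 and 0.0273). Among them were the peptide transporter Tap1 (1.66 ± 0.52), H2-D1 (1.16 ± 0.35) and B2m (0.95 ± 0.26). Disease-associated microglia genes were higher in 18 of 25 (8 adjusted over the list alone, 0 over all genes; 1.67e-08 and 0.0496). They included the receptors Clec7a (1.87 ± 0.46) and Axl (1.61 ± 0.36) and the integrin Itgax (1.65 ± 0.47). Nuclear genes of oxidative phosphorylation were higher in 30 of 30, none of them past the threshold alone (1.40e-08 and 0.0273). The MHC class II list (4 genes over all genes, 8 adjusted over the list alone) had 1.71e-14 and 0.00185.

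Neutrophil markers moved the other way, lower in 15 of 15 (7 adjusted over the list alone, 0 over all genes; adjusted p = 2.20e-11, and 0.0292 with an estimated correlation). S100a8, a granulocyte calcium-binding protein, stood at 5.48 ± 4.76 against 117 ± 91.0 CPM, S100a9 at 6.64 ± 7.25 against 134.8 ± 74.1 CPM. Ngp, a neutrophil granule protein, stood at 0.783 ± 0.672 against 66.2 ± 37.9. These 7 lists were called under every alternative, with adjusted p from 1.67e-19 to 0.0496. Another 7 lists, all up, lost their call with an estimated correlation. They were cell cycle (adjusted p = 2.34e-05, and 0.0935 with an estimated correlation), glycolysis (3.11e-06 and 0.0796) and phagocytosis and lysosome (3.34e-07 and 0.0677), with the scavenger receptor Msr1 at 2.94 ± 0.65. The others were inflammatory cytokines (0.000131 and 0.288), the mitochondrially encoded genes (8.56e-05 and 0.416), complement (0.0204 and 0.0935) and alternative activation (0.0146 and 0.172). The 7 ran from 4.97e-09 to 0.911 over the alternatives. Single left-out libraries ended alternative activation (MHC II+ ROS+ replicate 1, 0.0588, MHC II- ROS+ replicate 3, 0.0890) and complement (MHC II+ ROS+ replicate 2, 0.0828, MHC II- ROS+ replicates 1 and 3, 0.0704 and 0.0552). They also ended the mitochondrially encoded genes (MHC II- ROS+ replicate 1, 0.0589) and inflammatory cytokines (MHC II- ROS+ replicate 3, 0.132).

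**Figure D2:**
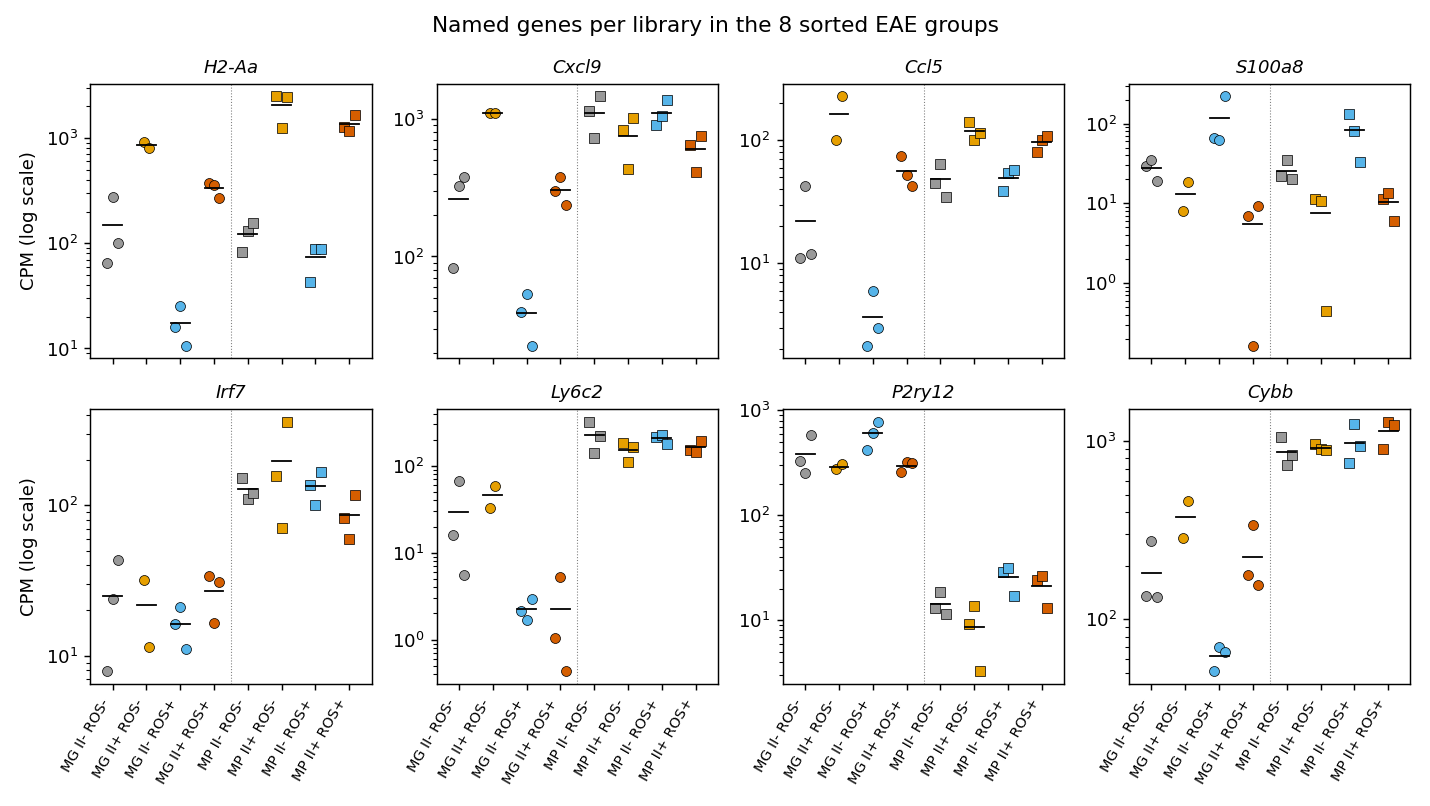
CPM on a log scale of 8 genes in every EAE library, by gate of microglia (MG) and macrophages (MP), with points for libraries and bars for group means. Cxcl9 and Ccl5 were higher in MHC II+ ROS+ than in MHC II- ROS+ microglia, and S100a8 stood at 5.48 against 117 CPM.

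The same pair of gates was compared in macrophages. The MHC II genes H2-Eb1 (519.0 ± 64.9 against 23.4 ± 2.88 CPM, n = 3 each; log2 fold change 4.47 ± 0.56, adjusted p = 0.000677), H2-Aa (4.22 ± 0.50) and H2-Ab1 (3.68 ± 0.59, adjusted p = 0.0209) rose. Cd74 stood at 2.79 ± 0.58 without passing (adjusted p = 0.409). Type I interferon genes were lower in 24 of 25 (0 genes both adjusted over the list alone and over all genes; adjusted p = 6.89e-16, and 0.00656 with an estimated correlation). Neutrophil markers were lower in 15 of 15 (9 adjusted over the list alone, 0 over all genes; 8.10e-24 and 0.00397). S100a8 stood at 10.3 ± 3.75 against 82.3 ± 50.3 CPM, S100a9 at 3.75 ± 3.18 against 84.7 ± 30.1 and the chemokine receptor Cxcr2 at a log2 fold change of -3.80 ± 1.00. Both lists missed with fry (adjusted p = 0.0551), the highest of their alternatives, which began at 3.64e-28. The MHC class II list (3 genes over all genes, 5 adjusted over the list alone; 1.89e-30 and 2.60e-05) was called under every alternative. Whether the type I interferon list differed between microglia and macrophages in this pair of gates was not tested.

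Monocyte markers were lower in 16 of 16 (2 adjusted over the list alone, 0 over all genes; adjusted p = 3.02e-10, and 0.0674 with an estimated correlation). Dendritic cell markers were higher in 15 of 16 (0 by either adjustment; 1.26e-06 and 0.0674), among them the actin bundler Fscn1 (4.45 ± 1.42). Interferon-gamma genes were lower in 17 of 20 (0 by either adjustment; 3.05e-07 and 0.0674). The disease-associated list (20 of 25 higher; 0.0313 and 0.791) was no longer called without MHC II+ ROS+ unnumbered-b (0.0844), MHC II+ ROS+ replicate 3 (0.0989) or MHC II- ROS+ replicate 3 (0.798). The range of these 4 lists over the alternatives was 1.06e-13 to 0.981. In all, 3 genes passed, and 244 had an unadjusted p below 0.05. The replicate numbers paired these libraries only with both unnumbered ones in table order, and as a block they gave 3 genes and took the complement list over the threshold (0.0568 before, 0.0459 with the block). Exchanged, they showed no pairing and gave 3 genes and 0.0447. H2-Ab1 lost its call without MHC II+ ROS+ unnumbered-a, MHC II+ ROS+ replicate 3 or any 1 of the MHC II- ROS+ libraries, so that 2 genes were then called. The count was 18 with DESeq2, 158 with voom and 6 with macrophages fitted alone.

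MHC II+ ROS+ microglia were set against the baseline to see what both markers add. RNAs of neurons and glia were far lower. S100b, a calcium-binding protein of astrocytes, stood at 0 counts against 19.98 ± 16.29 CPM (n = 3 each), at least 698-fold lower. Scrt1, a neuronal repressor with a purine or pyrimidine stretch of 101 bases, Sez6l and the exchanger gene Slc24a2 were at least 523-fold, 433-fold and 370-fold lower. The count ratio was 3967 (711.9 to 156700) for Dbn1, a protein of dendritic spines, and 3311 (594.3 to 130800) for Fabp7, a fatty acid carrier of astroglia. It was 2347 (421.2 to 92700) for the synaptic gene Cplx1 and 4087 (733.6 to 161400) for Ankrd43. In Dbn1, Fabp7 and Ankrd43 the baseline SD exceeded the mean (37.8 ± 63.2, 31.6 ± 42.0 and 38.97 ± 64.35 CPM). Ly6c2 fell by 3.74 on the log2 scale (SE 0.79, adjusted p = 0.0162). Genes that rose were Apbb3, an adaptor that binds the amyloid precursor protein (13.4 ± 10.6 against 0.346 ± 0.0649 CPM, log2 fold change 5.27 ± 1.28, adjusted p = 0.0420), and Gxylt1, which adds xylose to Notch (2.53 ± 0.53). Thada (2.45 ± 0.56), H2-M3, a nonclassical MHC class I gene (2.07 ± 0.48), and the splicing kinase Srpk1 (1.95 ± 0.48) rose too.

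In all, 232 genes were called, 10 higher and 222 lower, 55 of them predicted genes, with 2905 at an unadjusted p below 0.05. The genes of the MHC II gate did not pass against this baseline, where H2-Aa stood at 148 ± 114 CPM against 334.9 ± 57.4 in MHC II+ ROS+ (1.18 ± 0.45, adjusted p = 0.207). Of the fallen genes with a known transcript, 57.6% (118) held a purine or pyrimidine stretch of at least 50 bases, against 8.2% of genes matched for length, and 16 were mitochondrial. Leaving out MHC II+ ROS+ replicates 1, 2 and 3 gave counts of 99, 108 and 96 and ended 13, 11 and 13 of the 14 named calls. Leaving out baseline replicates 1, 2 and 3 ended 8, 4 and 10. Each of the 14 was lost without at least 1 library. The count was 78 without genes that hold long stretches, 135 with a minimum of 10 CPM, 125 with microglia fitted alone and 6 with the mitochondrial share as a covariate. It was 451 with voom and 1199 with DESeq2 (348 higher, 851 lower).

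Neuron, astrocyte and oligodendrocyte markers fell as lists. Neuron markers were lower in 10 of 10 (2 over all genes, 6 adjusted over the list alone; adjusted p = 1.57e-09, and 0.0114 with an estimated correlation). Snap25, a synaptic vesicle fusion protein, stood at 4.44 ± 6.86 against 229 ± 24.9 CPM. Astrocyte markers were lower in 8 of 10 (5 and 6; 1.05e-07 and 0.0114), the glutamate transporter Slc1a2 at 4.41 ± 4.06 against 214 ± 151 CPM. Oligodendrocyte markers were lower in 7 of 8 (1 and 3; 0.000544 and 0.0120), Mbp, the myelin basic protein, at 30.6 ± 18.5 against 218 ± 83.0 CPM. Over all alternatives the 3 lists ran from 2.74e-12 to 0.133, the last that of oligodendrocyte markers with the mitochondrial share as a covariate. The 12 mitochondrially encoded genes were all lower and all called by either adjustment (3.31e-17 and 0.0892), among them mt-Nd3 (-4.16 ± 0.58). They lay on the other side without passing once the mitochondrial share was a covariate (0.367, in a range from 4.96e-22). Monocyte markers were lower in 14 of 16 (2 and 10; 0.000102 and 0.271). Coagulation genes were lower in 15 of 23 (2 and 8; 0.00735 and 0.271), with F10 at -3.25 ± 0.81 (adjusted p = 0.0507, not passing).

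The MHC class II list was up (0 over all genes, 7 adjusted over the list alone; 0.000498, and 0.107 with an estimated correlation), as were phagocytosis genes (0.0203 and 0.517). Also up were immediate early and heat shock genes, which tissue dissociation induces (0.0293 and 0.679, turned without the 4 libraries with fewest genes, at 0.844). Erythroid (0.00717 and 0.271), neutrophil (0.00717 and 0.506) and endothelial markers (0.0293 and 0.361) were down. These 6 lists and those of monocytes and coagulation ran over the alternatives from 6.24e-07 to 0.844. Without baseline replicate 2 the monocyte (0.117), coagulation (0.125), erythroid (0.125), neutrophil (0.126) and endothelial (0.0794) calls ended. Without MHC II+ ROS+ replicate 2 the immediate early (0.473), endothelial (0.143), neutrophil (0.157) and phagocytosis (0.317) calls ended. Without baseline replicate 1 the immediate early (0.145), endothelial (0.0977) and phagocytosis (0.145) calls ended, and without baseline replicate 3 the immediate early (0.296), endothelial (0.0520) and erythroid (0.184) calls.

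**Figure D3:**
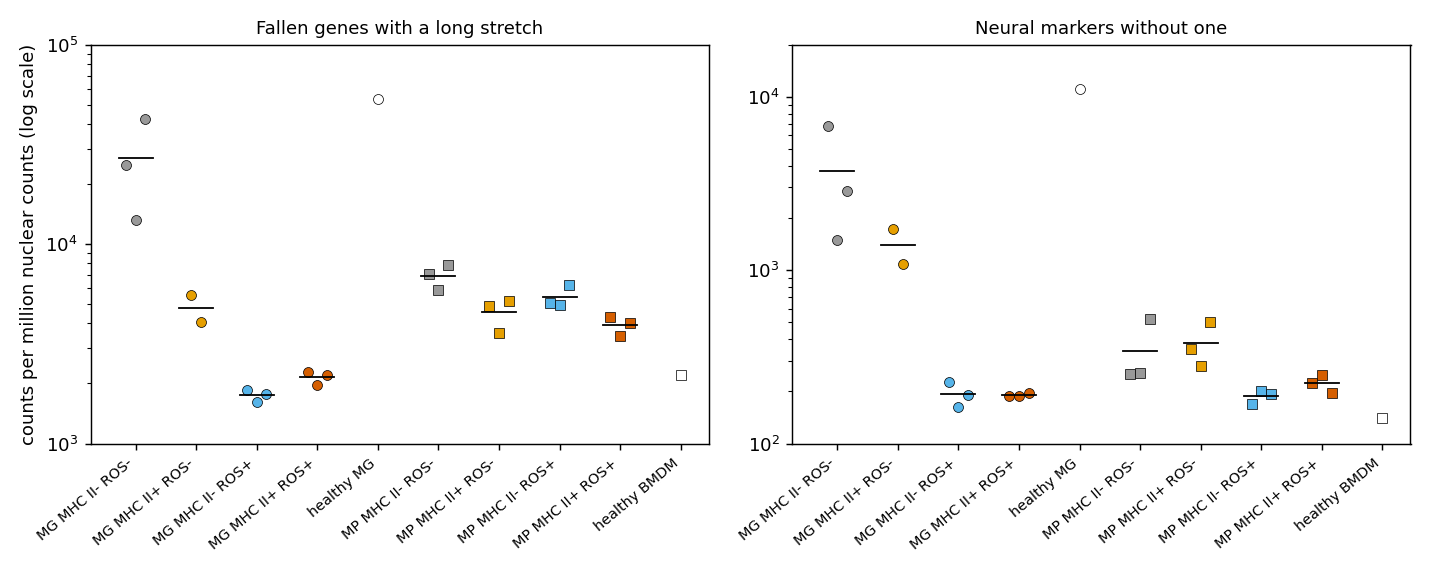
CPM among nuclear counts, on log scales, of fallen genes that hold a long purine or pyrimidine stretch (left) and of neural markers (right), with 1 point per library. The 3 microglia baseline libraries stood at 24900, 13190 and 42520 on the left and at 6821, 1487 and 2871 on the right. ROS+ microglia stood between 1623 and 2277 and between 162 and 225.3.

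MHC II- ROS+ microglia were set against the same baseline, to isolate the ROS gate. Rhox8, a homeobox gene of the X chromosome (35227957 to 35232121), stood at 1.38 ± 0.612 against 681 ± 545 CPM (n = 3 each; log2 fold change -8.94 ± 0.83, adjusted p = 1.06e-06). Fam124a (chromosome 14, 63174574 to 63227323) stood at 1.38 ± 0.251 against 671 ± 429 (-8.92 ± 0.70, adjusted p = 1.25e-07). Their transcripts hold purine or pyrimidine stretches of 194 and 167 bases. Neuronal genes were lower here too, Scrt1 (a stretch of 101 bases) at least 673-fold, with count ratios of 2178 (390.9 to 86030) for the kinase Dclk1 and 1828 (328.1 to 72210) for Snap91 of synaptic endocytosis. The ratio was 890.0 (246.4 to 7349) for the neurofilament gene Ina and 836.6 (231.6 to 6908) for Sez6l, and Ankrd43 stood at -10.18 ± 2.07. Cybb fell by 1.54 on the log2 scale (SE 0.34; 62.1 ± 9.89 against 181.1 ± 81.7 CPM, adjusted p = 0.0228). Ly6c2 fell by 3.70 (SE 0.79), H2-Aa by 3.09 (SE 0.48), H2-Eb1 by 3.1 (SE 0.52) and H2-Ab1 by 2.50 (SE 0.56). Genes that rose were Apbb3 (6.02 ± 1.32), the homeobox gene Pbx2 (2.84 ± 0.64) and Gxylt1 (81.7 ± 3.26 against 11.5 ± 5.01 CPM, 2.82 ± 0.53). The splicing kinase Clk1 (1.64 ± 0.39), Rgs2, which dampens G protein signalling (1.49 ± 0.34), and the cyclin Ccnl1 (1.29 ± 0.26) rose as well.

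Of 228 genes called, 11 were higher and 217 lower, 51 were predicted genes and 2737 genes had an unadjusted p below 0.05. Of the fallen genes with a known transcript, 55.4% (112) held a long stretch, against 8.1% of matched genes, and 18 were mitochondrial. The median log2 fold change of all genes was 0.12 here, and 0.01 with RLE scaling. With the replicate numbers as pairs, 198 genes passed. Without MHC II- ROS+ replicates 1, 2 and 3 the counts were 100, 114 and 101, and 13, 12 and 13 of the 19 named calls ended. Without baseline replicates 1, 2 and 3, 5, 6 and 8 ended. Gxylt1, Rhox8, Fam124a, H2-Aa and H2-Eb1 passed in all 6 cases. The count was 77 without genes that hold long stretches, 108 with microglia fitted alone and 0 with the mitochondrial share as a covariate. It was 450, 532 and 1140 without the 4 libraries with fewest genes, with voom and with DESeq2 (325 higher, 815 lower).

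Neuron markers fell (9 of 10 lower, 1 over all genes, 8 adjusted over the list alone; adjusted p = 1.88e-10, and 0.0107 with an estimated correlation). So did oligodendrocyte (7 of 8, 2 and 3; 0.000187 and 0.0107), astrocyte (9 of 10, 1 and 3; 3.89e-06 and 0.0150) and mitochondrially encoded genes (12 of 12, 12 and 12; 2.39e-24 and 0.0287). They ran from 3.79e-28 to 0.496 over the alternatives, the last that of the mitochondrially encoded genes, turned with the mitochondrial share as a covariate. Monocyte markers were lower in 15 of 16 (3 and 11; 5.39e-06 and 0.163). Disease-associated genes were lower in 20 of 25 (3 and 8; 0.000125 and 0.163), with Clec7a at -2.23 ± 0.46 and lysozyme (Lyz2) at -1.91 ± 0.47. Glycolysis genes were lower in 15 of 20 (3 over all genes, 10 lower and 1 higher adjusted over the list alone; 0.000616 and 0.163). Interferon-gamma genes (16 of 20 lower, 1 and 6; 0.000275 and 0.163) and type I interferon genes (18 of 25, 1 and 4; 0.000275 and 0.163) included Cxcl9 at -2.75 ± 0.47 and Oas3 at -2.38 ± 0.54. Both of these turned with the mitochondrial share as a covariate (0.549 and 0.893). Antioxidant genes were lower in 17 of 22 (1 and 4; 0.00409 and 0.196). The 6 lists ran from 7.87e-09 to 0.893 over the alternatives, and the antioxidant call ended without baseline replicate 2 (0.102).

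Immediate early and heat shock genes were higher in 17 of 22 (0 over all genes, 7 adjusted over the list alone; adjusted p = 0.00159, and 0.270 with an estimated correlation). Neutrophil markers were higher in 11 of 15 (0.00973 and 0.325; turned with the mitochondrial share as a covariate, at 0.960). Down were oxidative phosphorylation (0.000991 and 0.163), MHC class II (0.00270 and 0.163), coagulation (0.00409 and 0.163), erythroid markers (0.00435 and 0.163) and cell cycle (0.00892 and 0.264). So were MHC class I (0.00959 and 0.264), endothelial markers (0.0204 and 0.212; turned with a minimum of 10 CPM, at 0.891) and glutathione metabolism (0.0221 and 0.264; 6 lower and 1 higher adjusted over the list alone, 0 over all genes). B cell markers (0.0306 and 0.163; median log2 fold change 0.12, mean -0.18, with Ebf1 at -4.58 ± 1.08) and T cell markers (0.0356 and 0.389) completed them. Over all alternatives the 12 lists ran from 3.28e-06 to 0.960. Without baseline replicate 2 the calls of coagulation (0.102), erythroid markers (0.102), glutathione (0.102), MHC class I (0.106), T cell (0.147) and endothelial markers (0.0520) ended. Without baseline replicate 3 those of cell cycle (0.159), erythroid (0.154) and B cell markers (0.142) ended, and without baseline replicate 1 those of neutrophil (0.0501) and endothelial markers (0.0551). Without MHC II- ROS+ replicate 1 glutathione (0.0544) and T cell markers (0.0770) ended, and without replicate 3 MHC class I (0.0670), B cell (0.127) and endothelial markers (0.169).

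MHC II+ ROS- microglia (n = 2) were set against the baseline (n = 3), to isolate the MHC II gate. Beside H2-Aa (858.2 ± 71.8 against 148 ± 114 CPM; log2 fold change 2.54 ± 0.50, adjusted p = 0.0155), H2-Ab1 (2.78 ± 0.60), H2-Eb1 (2.50 ± 0.54) and Cd74 (2.84 ± 0.61), the MHC II transactivator Ciita (70.3 ± 46.9 against 2.06 ± 0.959 CPM; 5.07 ± 0.92, adjusted p = 0.00983) rose. Stat4, which carries interleukin-12 signals (8.06 ± 1.77), Socs2, a suppressor of cytokine signalling (104.0 ± 98.0 against 2.96 ± 1.35 CPM; 5.14 ± 0.78, adjusted p = 0.00271), and the ribonuclease Rnase6 (7.0 ± 1.53) rose too. So did Ccdc56 (7.67 ± 1.57), Arfrp1 (6.36 ± 1.21), Noc4l (64.4 ± 3.32 against 4.48 ± 1.85 CPM; 3.84 ± 0.81) and the peroxisomal thiolase Acaa1a (3.83 ± 0.81). Hmox1, the heme oxygenase induced by oxidative stress, stood at 201.4 ± 58.7 against 39.4 ± 5.85 CPM (2.35 ± 0.52, adjusted p = 0.0318). Lower were the sodium pump subunit Atp1b1 (at least 483-fold, from 44.7 ± 23.9 CPM), Ankrd43 (at least 421-fold), the synaptic gene Syn1 (at least 250.5-fold), Zadh2 (at least 192-fold), Mrpl55 (at least 171-fold) and Prr24 (at least 159-fold). The count ratio was 388 (107.5 to 3208) for Tppp, a tubulin-binding protein of oligodendrocytes, and 355 (63.8 to 14040) for Timm8a1.

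Here 178 genes passed, 60 higher and 118 lower, 32 of them predicted genes, with 3694 at an unadjusted p below 0.05. A share of 43.9% (47) of the fallen genes with a known transcript held a long stretch, against 7.9% of matched genes. None of the 21 named calls held without each library in turn. Without baseline replicates 1, 2 and 3, 11, 4 and 18 ended, and 13 and 16 without MHC II+ ROS- replicates 1 and 2, which leaves a lone library assumed to vary like the other groups. The count was 303 without baseline replicate 2, 52 without baseline replicate 3 and 77 without MHC II+ ROS- replicate 2. It was 0 with voom and library weights, 43 with microglia fitted alone, 95 without genes that hold long stretches and 116 with the replicate block. It was 553 without the 4 libraries with fewest genes and 2446 with DESeq2 (633 higher, 1813 lower).

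The MHC class II list rose (6 of 14 over all genes, 9 adjusted over the list alone; adjusted p = 3.33e-07, and 0.0452 with an estimated correlation, the highest in a range that began at 5.95e-09). Another 17 lists lost their call with an estimated correlation. Disease-associated genes were higher in 23 of 25 (0 and 6; 6.12e-06 and 0.157), among them the chemokine gene Ccl6 (2.02 ± 0.57). Inflammatory cytokine genes were higher in 17 of 26 (2 over all genes, 6 higher and 1 lower adjusted over the list alone; 8.43e-05 and 0.243), with Ccl5 at 2.91 ± 0.56 and Cxcl9 at 2.08 ± 0.49. Phagocytosis genes (23 of 27 higher, 0 and 4; 8.43e-05 and 0.196) and glycolysis genes (18 of 20, 0 and 6; 0.000128 and 0.196, with the glucose transporter Slc2a1 at 1.69 ± 0.43) were higher. So were MHC class I genes (13 of 14, 1 and 6; 0.000349 and 0.196, with Psme1 at 1.5 ± 0.36) and alternative activation genes (10 of 16, 1 and 2; 0.00113 and 0.157), and neuron markers were lower in 10 of 10 (0 by either adjustment; 0.000137 and 0.157). All 7 together ran over the alternatives from 2.62e-07 to 0.243. Up as well were type I interferon (0.00385 and 0.243), C-type lectin and Toll-like receptors (0.00576 and 0.232), oxidative phosphorylation (0.00704 and 0.232) and complement (0.0120 and 0.157). So were antioxidant defence (0.0218 and 0.287; median 0.52, mean -0.20), border-associated macrophages (0.0417 and 0.199), NADPH oxidase (0.0417 and 0.199; median 0.24, mean -0.15) and dendritic cell markers (0.0446 and 0.373). Endothelial (0.0446 and 0.283) and astrocyte markers (0.0474 and 0.243) were down. The 10 ran from 0.000422 to 0.756 over the alternatives. Leaving out baseline replicate 1 ended C-type lectin (0.0616), NADPH oxidase (0.108), antioxidant (0.145), complement (0.0671), astrocyte (0.108), border-associated (0.0948), dendritic (0.0706), endothelial (0.108) and oxidative phosphorylation (0.0706). Leaving out baseline replicate 3 ended NADPH oxidase (0.0866), astrocyte (0.119), border-associated (0.114), dendritic (0.114) and endothelial (0.0713). Leaving out MHC II+ ROS- replicate 1 ended NADPH oxidase (0.0547), complement (0.0576), border-associated (0.593), dendritic (0.296) and endothelial (0.154). Leaving out MHC II+ ROS- replicate 2 ended NADPH oxidase (0.217), antioxidant (0.124), astrocyte (0.433) and endothelial (0.0989), and leaving out baseline replicate 2 ended endothelial markers (0.0715).

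MHC II+ ROS+ (n = 3) were also set against MHC II+ ROS- microglia (n = 2), the ROS contrast among MHC II+ cells. Nrg1, the growth factor neuregulin, stood at 0.136 ± 0.0648 against 23.02 ± 22.04 CPM (log2 fold change -7.33 ± 1.03, adjusted p = 0.00467). Also lower were Nxn, the redox protein nucleoredoxin (-9.43 ± 2.25), Mtss1l (-8.88 ± 2.11), Nrbp2 (-8.57 ± 1.97) and Clec1b, a receptor of podoplanin (-8.35 ± 1.70). The neutrophil chemokine gene Cxcl3 (-8.11 ± 1.73), the phosphodiesterase Pde5a (-6.79 ± 1.39), B3gnt5 (-5.97 ± 1.38), Ly6c2 (2.24 ± 2.62 against 45.6 ± 17.7 CPM; -4.36 ± 0.85) and Clec4e (9.77 ± 7.44 against 148.9 ± 77.9 CPM; -3.93 ± 0.86) were lower too. Hmox1 stood at -2.13 ± 0.52 without passing (adjusted p = 0.05002). Higher were Dnmt3l-ps1, a pseudogene whose reads can belong to its parent gene (at least 224.9-fold), Aste1 (at least 184-fold) and the phosphatase Ppm1l (at least 117-fold). The count ratio was 262 (72.5 to 2161) for Zfp748, 222 (61.4 to 1831) for the cyclophilin Ppih, 218 (60.5 to 1803) for Narg2, 172 (47.7 to 1424) for Zfp40 and 168 (46.6 to 1391) for Sgsm3.

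Of 194 genes called, 66 were higher and 128 lower, 25 were predicted genes, 10 mitochondrial, and 3450 had an unadjusted p below 0.05. In MHC II+ ROS- against baseline the 128 had a median log2 fold change of 1.58 and the 66 of -4.99, so the 66 were mostly low there. Without MHC II+ ROS+ replicates 1, 2 and 3 the counts were 73, 45 and 35, and 13, 15 and 16 of the 18 named calls ended. Without MHC II+ ROS- replicates 1 and 2, 11 and 10 ended. Nrg1 passed in all 5 cases. The count was 0 with the mitochondrial share as a covariate, 2 with microglia fitted alone, 7 with voom and 90 with the block and exchanged libraries. It was 327, 623 and 2258 with a minimum of 10 CPM, without the 4 libraries with fewest genes and with DESeq2 (1455 higher, 803 lower).

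All 22 lists called here were lower in MHC II+ ROS+, and none was called with an estimated correlation. Monocyte markers were lower in 12 of 16 (4 over all genes, 10 adjusted over the list alone; adjusted p = 6.72e-07, and 0.137 with an estimated correlation). Disease-associated genes were lower in 21 of 25 (2 and 8; 9.56e-06 and 0.137), with Ccl6 at -3.19 ± 0.59 and Lyz2 at -2.61 ± 0.51. Glycolysis genes were lower in 16 of 20 (3 over all genes, 8 lower and 1 higher adjusted over the list alone; 5.07e-05 and 0.137). C-type lectin and Toll-like receptor genes were lower in 18 of 21 (1 and 5; 6.28e-05 and 0.137) and antioxidant genes in 16 of 22 (1 and 6; 0.000325 and 0.137). The mitochondrially encoded genes were lower in 12 of 12 (7 and 12; 5.50e-14 and 0.137) and turned with the mitochondrial share as a covariate (0.626). These 6 lists ran from 2.85e-16 to 0.626 over the alternatives. The other 16 lists had adjusted p from 0.00121 (astrocyte markers, 2 and 5) to 0.0483. With an estimated correlation they lay from 0.137 to 0.461, in a range from 2.01e-05 to 0.879 over the alternatives. All of these but coagulation lost their call without at least 1 of the 5 libraries, with adjusted p from 0.0529 to 0.720. Astrocyte markers missed without MHC II+ ROS- replicate 1 (0.0708), and without MHC II+ ROS- replicate 2 NADPH oxidase (0.00402 and 0.137, then 0.0716) and inflammatory cytokines (0.00315 and 0.348, then 0.0529). Type I interferon genes (0.0451 and 0.410) missed without MHC II+ ROS+ replicates 1 and 3 (0.108 and 0.0758) and MHC II+ ROS- replicates 1 and 2 (0.184 and 0.109) and turned with the mitochondrial share as a covariate (0.735). Neutrophil markers (0.0483 and 0.461) missed without MHC II+ ROS+ replicate 2 (0.401) and MHC II+ ROS- replicate 2 (0.505) and turned without the 4 libraries with fewest genes (0.879).

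Macrophage gates were set against their own baseline likewise. In MHC II+ ROS+ macrophages H2-Eb1 (519.0 ± 64.9 against 34.4 ± 6.10 CPM, n = 3 each; log2 fold change 3.92 ± 0.54, adjusted p = 0.00451), H2-Aa (1369 ± 257 against 123.6 ± 37.4 CPM; 3.47 ± 0.49) and Pdgfb, a growth factor of the PDGF family (3.26 ± 1.09 against 0.0942 ± 0.0274 CPM; 5.05 ± 0.79, adjusted p = 0.0155), rose. These were the 3 genes called, with 1968 at an unadjusted p below 0.05. Type I interferon genes were lower in 24 of 25 (0 over all genes, 5 adjusted over the list alone; adjusted p = 4.10e-12, and 0.0294 with an estimated correlation, the highest in a range from 1.98e-14). Oas2 stood at -1.83 ± 0.57 and Stat2 at -1.06 ± 0.35. The mitochondrially encoded genes were lower in 12 of 12 (0 and 12; 1.15e-23 and 0.0423, from 1.55e-27 to 0.609 over the alternatives). The MHC class II list was up (2 and 7; 5.51e-09 and 0.0229, called under every alternative). Lists that lost the call with an estimated correlation were interferon-gamma genes, lower in 19 of 20 (0.000611 and 0.304, turned with the mitochondrial share as a covariate at 0.973), neutrophil (7.12e-06 and 0.304) and monocyte markers (7.40e-05 and 0.304; the proteoglycan Vcan at -3.10 ± 0.74). Upward, cell cycle (0 and 4; 0.00329 and 0.383) and dendritic cell markers (0 and 2; 0.0390 and 0.598) lost it too. Their 5 ranges over the alternatives lay within 8.45e-08 to 0.973. Dendritic cell markers missed without MHC II+ ROS+ unnumbered-a (0.151), MHC II+ ROS+ unnumbered-b (0.0936), baseline replicate 1 (0.0527) or baseline replicate 2 (0.127), and cell cycle without MHC II+ ROS+ unnumbered-b (0.0936). No gene was called without baseline replicate 1 or baseline replicate 3, and 5 were without baseline replicate 2. The count was 21 without a filter, 29 with a minimum of 10 CPM, 96 without the 4 libraries with fewest genes, 205 with voom, 523 with DESeq2 and 0 with the mitochondrial share as a covariate.

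Between MHC II- ROS+ macrophages and their baseline edgeR called 0 genes, with 1772 at an unadjusted p below 0.05. DESeq2 called 395, voom 16, edgeR without a filter 8, and edgeR without the 4 libraries with fewest genes 52. Cybb stood at 982.6 ± 247.8 against 874.0 ± 159.7 CPM (0.17 ± 0.33) and H2-Aa at 73.4 ± 26.4 against 123.6 ± 37.4 (-0.75 ± 0.44). The mitochondrially encoded genes were lower in 12 of 12 (0 over all genes, 12 adjusted over the list alone; adjusted p = 5.88e-26, and 0.0908 with an estimated correlation, from 1.71e-31 to 0.414 over the alternatives). No other list was called.

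In MHC II+ ROS- macrophages Tpm1, an actin-binding tropomyosin, stood at 36.3 ± 26.2 against 0.570 ± 0.395 CPM in the baseline (n = 3 each; log2 fold change 5.97 ± 0.91, adjusted p = 0.0103). Hpgd, which degrades prostaglandins, stood at 0.354 ± 0.314 against 11.3 ± 5.24 (-4.92 ± 0.88, adjusted p = 0.0387). H2-Eb1 (4.74 ± 0.56), H2-Aa (4.06 ± 0.50) and H2-Ab1 (3.73 ± 0.59) rose. In all, 8 genes passed, 6 higher and 2 lower, 1 of them a predicted gene, with 2126 at an unadjusted p below 0.05. The MHC class II list rose (3 of 14 over all genes, 6 adjusted over the list alone; adjusted p = 4.75e-13, and 0.00316 with an estimated correlation, from 1.11e-16 over the alternatives). Type I interferon genes were lower in 23 of 25 (0 by either adjustment; 1.07e-06 and 0.149). Neutrophil (1.67e-05 and 0.346), monocyte (0 and 2; 0.00128 and 0.585), interferon-gamma (0.0223 and 0.609) and oligodendrocyte lists (0.0272 and 0.149) were down. Dendritic cell markers (0 and 2; 0.0227 and 0.609), oxidative phosphorylation (0 and 1; 0.0227 and 0.585) and disease-associated genes (0.0277 and 0.756) were up. From 1.16e-09 to 0.756 was the range of these 8 over the alternatives. Calls ended without baseline replicate 1 in the interferon-gamma (0.0571) and oligodendrocyte lists (0.230), without baseline replicate 2 in dendritic markers (0.0869) and oxidative phosphorylation (0.115), and without baseline replicate 3 in the disease-associated (0.756), interferon-gamma (0.431) and oxidative phosphorylation lists (0.179). They ended without MHC II+ ROS- replicate 1 in the disease-associated (0.198), interferon-gamma (0.198), dendritic (0.314), oligodendrocyte (0.0536) and oxidative phosphorylation lists (0.198). Without MHC II+ ROS- replicate 2 they ended in the interferon-gamma (0.293), dendritic (0.157) and oligodendrocyte lists (0.157), and without MHC II+ ROS- replicate 3 in the disease-associated list (0.186). Of the 5 named genes, H2-Eb1 and H2-Aa passed without each library in turn. The count was 3 without baseline replicate 1 or baseline replicate 3 and 5 without MHC II+ ROS- replicate 2, and 24 and 607 without the 4 libraries with fewest genes and with DESeq2.

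Between MHC II+ ROS+ and MHC II+ ROS- macrophages edgeR called 0 genes (984 at an unadjusted p below 0.05), voom 2 and DESeq2 102. P2ry12 stood at 21.2 ± 7.18 against 8.69 ± 5.22 CPM (1.29 ± 0.44, adjusted p = 0.892). The mitochondrially encoded genes were lower in 12 of 12 (0 over all genes, 12 adjusted over the list alone; adjusted p = 3.14e-23, and 0.135 with an estimated correlation). Homeostatic microglia genes (19 of 25 higher; 0.000755 and 0.583), cell cycle genes (18 of 25; 0.00441 and 0.716) and T cell markers (14 of 16; 0.000225 and 0.583) were up with 0 members passing by either adjustment. The T cell list turned with a minimum of 10 CPM (0.856), and over all alternatives these 4 lists ran from 1.17e-25 to 0.856. Without MHC II+ ROS- replicate 1 the homeostatic (0.275) and cell cycle (0.254) calls ended, and without MHC II+ ROS+ unnumbered-b the cell cycle call (0.288).

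Whether MHC II+ ROS+ differed from baseline in another way in microglia than in macrophages was tested directly. Type I interferon genes were relatively higher in microglia in 25 of 25 (0 over all genes, 7 adjusted over the list alone; adjusted p = 4.45e-07, and 0.112 with an estimated correlation). Oas2 stood at 89.6 ± 48.0 CPM in MHC II+ ROS+ and 27.0 ± 13.5 in baseline microglia, and at 120.4 ± 45.1 and 428 ± 198 in macrophages (n = 3 each; difference 3.56 ± 0.81). Stat2 stood at 295.2 ± 71.5 and 136.2 ± 16.3 against 217.2 ± 69.7 and 451.9 ± 94.3 (2.17 ± 0.50) and Mx1 at 59.4 ± 28.3 and 12.9 ± 9.35 against 62.6 ± 18.3 and 206 ± 120 (3.92 ± 0.98). Interferon-gamma genes followed in 17 of 20 (0 by either adjustment; 0.00992 and 0.666), a call that ended without microglia baseline replicate 1 (0.0606) or macrophage baseline replicate 3 (0.104). Astrocyte (9 of 10 lower, 1 and 5; 1.54e-05 and 0.0605) and neuron markers (9 of 10, 0 and 4; 3.79e-05 and 0.112) were relatively lower in microglia. The 4 lists ran over the alternatives from 6.07e-09 to 0.666.

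The named genes were all relatively lower in microglia. Fabp7 differed by -16.44 ± 3.02, at 0.00797 ± 0.0138 and 31.6 ± 42.0 CPM in MHC II+ ROS+ and baseline microglia and at 2.08 ± 1.84 and 0.0508 ± 0.0880 in macrophages. The chemokine receptor gene Ccr4, whose transcripts hold a stretch of 116 bases, differed by -9.03 ± 1.69 (0.191 ± 0.0558 and 30.6 ± 23.6 against 1.38 ± 0.860 and 0.417 ± 0.454 CPM). Scd1, the stearoyl-CoA desaturase, differed by -11.46 ± 2.34. Akap6 (-14.37 ± 2.99), Dbn1 (-14.36 ± 3.11), Zfp365 (-14.18 ± 2.68), the G protein subunit Gnao1 (-12.12 ± 2.43) and Rtn1 (-8.25 ± 1.72), all of them expressed in neurons, completed the 8. Since several groups held only a few counts, these fitted values are no measure of size. In all, 56 genes passed, 56 lower and 0 higher, with 2495 at an unadjusted p below 0.05, 28 holding a long stretch and 17 being predicted genes. All 8 named calls ended without any 1 of the 3 microglia MHC II+ ROS+ libraries or without macrophage baseline replicate 1. The calls ended numbered 7 without macrophage baseline replicate 2 or replicate 3, 4 and 6 without microglia baseline replicates 1 and 3, and 5, 2 and 4 without macrophage MHC II+ ROS+ unnumbered-a, unnumbered-b and replicate 3. The count was 24 and 29 without microglia MHC II+ ROS+ replicates 1 and 3, 30 without microglia baseline replicate 3 and 36 without macrophage MHC II+ ROS+ unnumbered-a. It was 36, 36 and 30 without macrophage baseline replicates 1, 2 and 3. The count was 16 without genes that hold long stretches, 37 with the mitochondrial share as a covariate, 86 without the 4 libraries with fewest genes and 773 with DESeq2 (201 relatively higher, 572 lower).

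**Figure D4:**
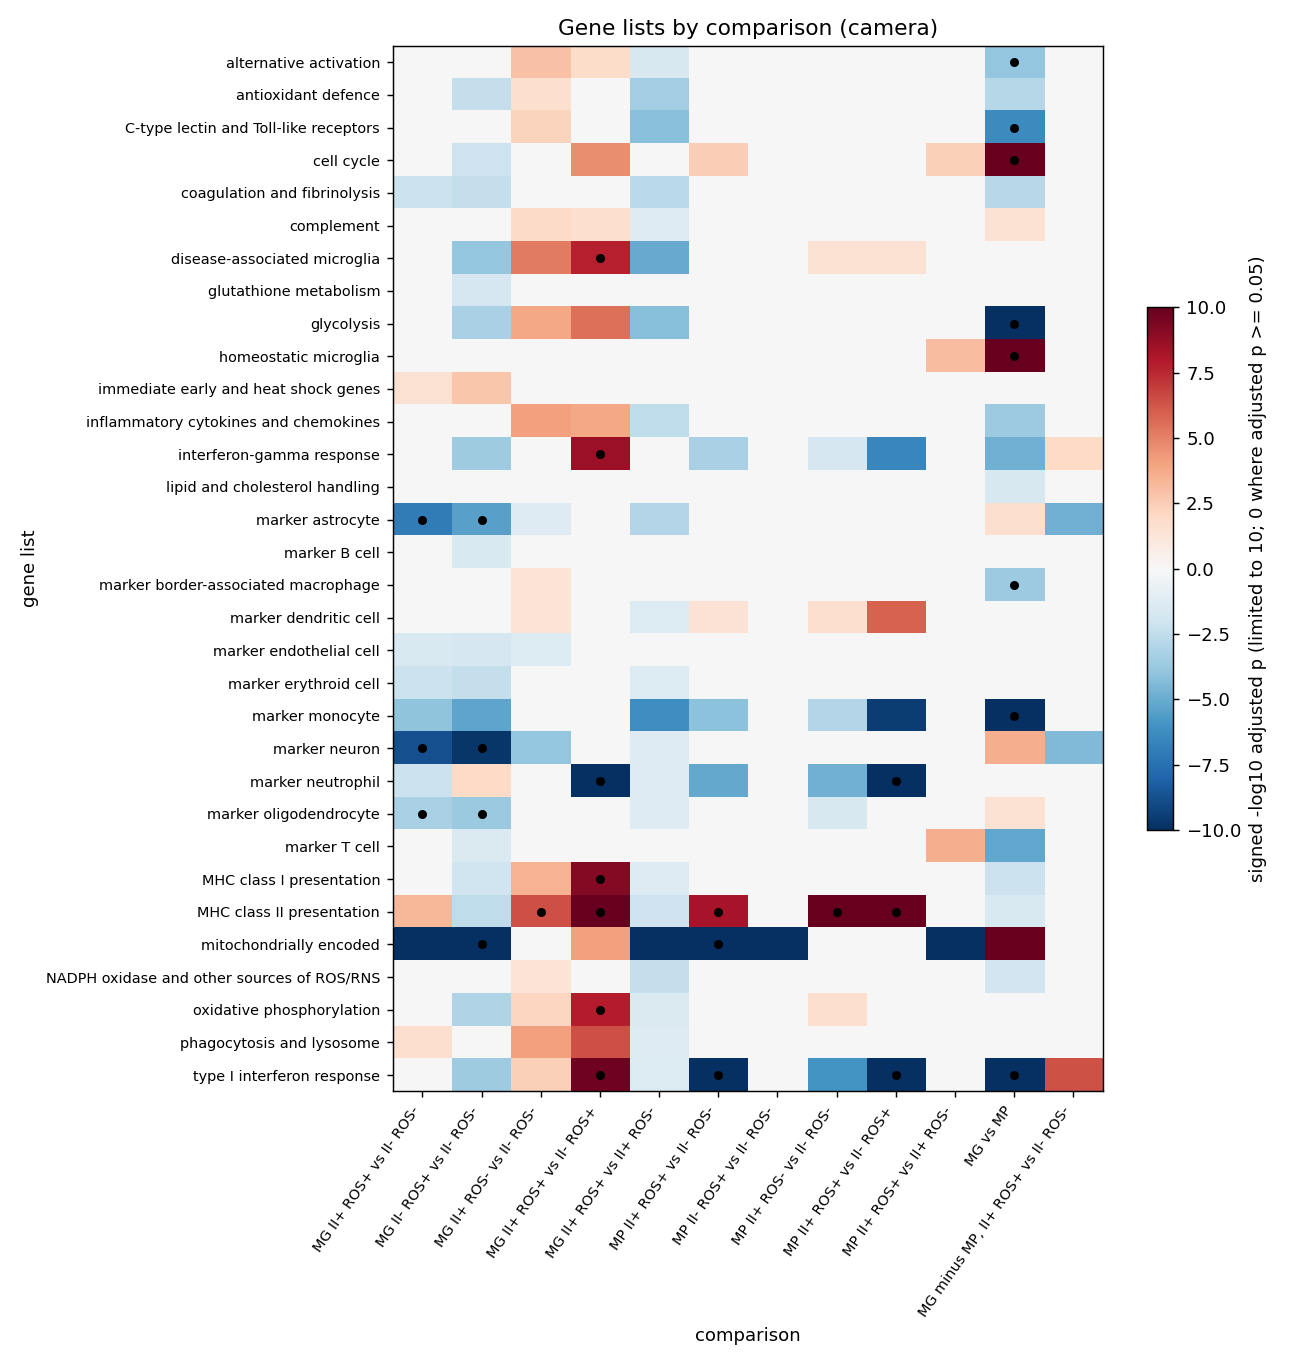
Gene lists (vertical axis) by comparison (horizontal axis, MG for microglia and MP for macrophages), coloured by the signed -log10 of the adjusted p, limited to 10 and set to 0 where the list was not called. Black dots mark the 30 calls, of 143, also made with an estimated correlation. Of the 33 lists, 32 were called at least once and natural killer cell markers in no comparison.

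For each of the 10 pairs of gates the authors' deposited table gave 20484 genes a value, and in it no gene had a false discovery rate below 0.05 or 0.1. The lowest per pair in the authors' deposited table lay between 0.302 and 1, with that of MHC II- ROS+ microglia against baseline computed from the p-values there. The sign of the log2 fold change in the authors' deposited table was that found here for 99.1% to 99.8% of 18500 shared genes. Every gene called here that had a value in the authors' deposited table had the same sign there.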

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

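The tests of the 3 patterns were chosen after the result they bear on was seen. So were the divisions of libraries, except that for the difference between cell types, and the alternatives that the methods list as added.

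MHC II+ ROS+ against baseline differed between microglia and macrophages in 56 genes, all relatively lower in microglia (with DESeq2 201 of 773 were higher). Among 100 divisions of the 12 libraries 7 gave as many, the highest of the others 95, so chance cannot be excluded. The named genes differed by -16.44 (Fabp7), -14.37 (Akap6), -14.36 (Dbn1), -14.18 (Zfp365), -12.12 (Gnao1), -11.46 (Scd1), -9.03 (Ccr4) and -8.25 (Rtn1) on the log2 scale, and each lost its call without at least 4 of the 12 libraries in turn. By list, type I interferon (adjusted p = 4.454e-07) and interferon-gamma genes (0.009917) were relatively higher and astrocyte (1.542e-05) and neuron markers (3.787e-05) relatively lower in microglia. They had 0.112, 0.666, 0.0605 and 0.112 with an estimated correlation and from 6.07e-09 to 0.666 over all alternatives.

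RNA lower than in the microglia baseline is the first pattern weighed, in 279 genes that fell in MHC II+ ROS+ or MHC II- ROS+ microglia. The mitochondrial share of the libraries cannot be told apart from the ROS gate, with which it goes. With the share as a covariate the median log2 fold change of the fallen nuclear genes went from -6.53 to -6.05 in MHC II+ ROS+ and from -5.50 to -4.68 in MHC II- ROS+. Their median SE grew from 1.12 to 2.11 and from 0.92 to 2.16, which ended all but 6 of 206 and all of 199 calls. Reads of purine or pyrimidine repeats may make up part of the pattern, since 51.7% (135) of the 261 fallen genes with a known transcript held a stretch of at least 50 bases against 8.3% of length-matched genes. RNA of neural cells stays open for these genes too. The ratio of their counts to those of neural markers differed 4.05-fold over the 3 baseline libraries (3.65 to 14.8), but the ratio of neuron to oligodendrocyte markers also ran from 0.602 to 6.73. RNA of neurons and glia carried by debris or cells in the CD45lo CD11b+ gate may make up another part, since 21 of 25 neural markers without such a stretch were lower in both ROS+ groups, Snap25, Mbp and Slc1a2 standing at 229, 218 and 214 CPM in the baseline. A change within microglia stays untested beside these.

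Neutrophil markers lower in MHC II+ ROS+ than in MHC II- ROS+ cells are the second pattern. A single library as its source is argued against by leaving out each of the 12 libraries, under which the adjusted p of the list reached at most 2.05e-09. Neutrophils, which are CD11b+ and carry little MHC II but which the CD45lo gate of microglia would remove, may have been sorted with the MHC II- ROS+ cells, where S100a8 and S100a9 stood at 117 and 134.8 CPM in microglia and 82.3 and 84.7 CPM in macrophages. All 15 markers were lower in both cell types, but they define the pattern, so such cells cannot be told apart from a change of these genes within microglia and macrophages. The list holds no gene picked from these libraries.

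The library labelled healthy bone marrow-derived macrophage is the third pattern, for its neutrophil and erythroid genes. Whether it was swapped with another library cannot be told, as S100a8 (at most 206.3 CPM elsewhere, 10230 CPM here) is one of these genes. Other bone marrow cells in that library may carry these genes. The 20 of 20 neutrophil and erythroid markers above all 3 macrophage baseline libraries define the pattern and decide nothing, and of B cell markers 5 of 7 lay above. A wrong label on this 1 library stays open too, and no biological explanation was tested.

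The other comparisons with at least 3 libraries per group were divided in other ways too. For microglia against macrophages 1 of 100 divisions, the real one, gave as many genes (4099, the highest other 18), so chance is excluded there. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real values and the highest others were 232 and 4 for MHC II+ ROS+ and 228 and 1 for MHC II- ROS+ microglia against baseline, and 6 and 2 for MHC II+ ROS+ against MHC II- ROS+ microglia. In macrophages they were 3 and 0 for MHC II+ ROS+, 0 and 0 for MHC II- ROS+ and 8 and 29 for MHC II+ ROS- against baseline, 3 and 0 for MHC II+ ROS+ against MHC II- ROS+ and 0 and 0 against MHC II+ ROS-. As many genes as the real split, itself counted, were given by 1, 1, 1, 1, 10, 2, 1 and 10 of the 10 splits in that order. The split with 29 genes set apart macrophage baseline replicates 1 and 3 and MHC II+ ROS- replicate 3. They had fewest genes and highest mitochondrial shares (from 45.55%, others to 43.83%). Where replicate numbers paired the libraries, in macrophages only in table order, the highest other among the splits that parted 3 pairs was 0 and among those that parted fewer 1 for MHC II- ROS+ microglia against baseline, and 0 and 0 for MHC II+ ROS+ against MHC II- ROS+ macrophages.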

How the results depend on the processing

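Of the alternatives, those with voom, the mitochondrial share as a covariate, mitochondrial genes left out, the 4 libraries with fewest genes left out, a minimum of 10 CPM, long stretches left out, the exchanged block and, for list tests, RLE and no filter were chosen after seeing the data. No named gene that was called turned its direction under any alternative run, and of all called lists 12 values turned. Over every result, 159 counts stayed within 1.5 times and 87 did not, 642 gene values lost and 78 gained a call. Another 4163 kept theirs or, where not called, stayed within 1 SE, and 96 without a call moved further. Of list values, 2288 kept and 478 lost theirs. Where a number differs below, the cause was not tested, except that fewer genes or libraries were tested where these were left out. A pseudocount alternative does not apply, since counts exist. Of the EAE groups depth limited the microglia baseline most (4883612 to 8710038 nuclear counts).

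Comparisons are given in the order microglia MHC II+ ROS+, MHC II- ROS+ and MHC II+ ROS- against baseline, MHC II+ ROS+ against MHC II- ROS+ and against MHC II+ ROS-, the same in macrophages, both cell types, and their difference. Called were 232, 228, 178, 6, 194, 3, 0, 8, 3, 0, 4099 and 56 genes. With 1 library left out the counts ran from 96 to 278, 100 to 262, 52 to 303, 2 to 10, 35 to 257, 0 to 5, 0 to 0, 3 to 9, 2 to 3, 0 to 0, 3399 to 4243 and 24 to 71, where a group of 1 is assumed to vary like the others. DESeq2 gave 1199, 1140, 2446, 237, 2258, 523, 395, 607, 18, 102, 5385 and 773. Limma voom with library weights gave 451, 532, 0, 60, 7, 205, 16, 12, 158, 2, 4392 and 78. With the mitochondrial share as a covariate, which goes with the ROS gate, the counts were 6, 0, 187, 6, 0, 0, 0, 5, 3, 0, 1088 and 37. Without the 4 libraries with fewest genes they were 195, 450, 553, 5, 623, 96, 52, 24, 4, 0, 4468 and 86. With a minimum of 10 CPM they were 135, 199, 265, 11, 327, 29, 28, 10, 3, 0, 2378 and 48. Without genes that hold long stretches they were 78, 77, 95, 5, 151, 3, 0, 8, 3, 0, 3607 and 16. With no filter they were 229, 197, 132, 6, 213, 21, 8, 9, 3, 0, 3854 and 67. With the replicate number as a block they were 206, 198, 116, 7, 133, 4, 5, 7, 3, 0, 3840 and 49, and with both unnumbered libraries exchanged 190, 178, 103, 6, 90, 3, 0, 6, 3, 0, 3770 and 45. Each cell type fitted alone gave 125, 108, 43, 1 and 2 for microglia and 4, 0, 8, 6 and 0 for macrophages. RLE factors and mitochondrial genes left out moved no count by more than 1.5 times.

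Of the 143 list calls, 30 were also made with an estimated correlation (30 called in all), 76 with fry (87) and 82 with the mitochondrial share as a covariate (88). The other alternatives that kept every library or left out 4 made from 102 to 139 of them (115 to 151 in all). Where the replicate numbers paired libraries, in macrophages only in table order, the block ended no list call, and complement in macrophage MHC II+ ROS+ against MHC II- ROS+ went from 0.0568 to 0.0459. The values that turned are given with the range over all alternatives of that list. Without the 4 libraries with fewest genes they were neutrophil markers in microglia MHC II+ ROS+ against MHC II+ ROS- (adjusted p = 0.879, range 0.0181 to 0.879) and immediate early genes in MHC II+ ROS+ against baseline (0.844, range 0.000466 to 0.844). With the mitochondrial share as a covariate they were interferon-gamma genes in macrophage MHC II+ ROS+ against baseline (0.973, range 1.07e-05 to 0.973). So were mitochondrially encoded (0.626, range 2.85e-16 to 0.626) and type I interferon genes (0.735, range 0.0248 to 0.735) in microglia MHC II+ ROS+ against MHC II+ ROS-, and mitochondrially encoded genes in MHC II+ ROS+ against baseline (0.367, range 4.96e-22 to 0.367). In MHC II- ROS+ against baseline they were interferon-gamma (0.549, range 3.49e-05 to 0.549), neutrophil (0.960, range 0.00234 to 0.960), mitochondrially encoded (0.496, range 3.79e-28 to 0.496) and type I interferon genes (0.893, range 4.57e-05 to 0.893). With a minimum of 10 CPM they were T cell markers in macrophage MHC II+ ROS+ against MHC II+ ROS- (0.856, range 1.74e-10 to 0.856) and endothelial markers in microglia MHC II- ROS+ against baseline (0.891, range 0.00754 to 0.891). In the healthy microglia library RLE factors gave -2.55 for type I interferon genes (-2.83 before) and -2.22 for interferon-gamma genes (-2.39 before), and leaving out a baseline library gave -2.51 to -2.41 for type I interferon genes. In the healthy bone marrow-derived macrophage library it gave -1.84 to -1.32 for homeostatic genes (-1.99 before), -4.02 to -3.46 for inflammatory cytokines (-4.16 before) and 8.10 to 8.39 for erythroid markers (8.82 before).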

Other observations

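Microglia from a healthy mouse (1 library, not tested) held less interferon and cell cycle RNA than the baseline gate of EAE microglia. The interferon-induced membrane protein gene Bst2 stood at 0.536 CPM against 48.3 ± 33.2 CPM in the 3 baseline libraries. The cyclin Ccna2 stood at 0.715 against 51.01 ± 36.23 and the kinetochore motor Cenpe at 0.715 against 85.0 ± 9.69. Of 25 type I interferon genes 18 lay below all 3 baseline libraries (median log2 ratio -2.83, below every one of 10000 random lists of matched expression), of 19 interferon-gamma genes 14 (-2.39) and of 25 cell cycle genes 24 (-4.67). So did 13 of 14 MHC class I genes (-1.88), 9 of 17 complement genes (-1.93) and 16 of 25 disease-associated genes (-1.28). Tmem119 stood at 669.8 against 301.9 ± 93.7 CPM and P2ry12 at 478.7 against 360.9 ± 160.1, and the homeostatic list had a median log2 ratio of 0.26 (percentile 76.1 of its random lists). Cybb stood at 34.0 against 168.5 ± 76.0 CPM. The library had 95.4% of its counts on mitochondrial genes, so that nuclear genes rested on fewer counts. Fallen genes with a long stretch and neural markers stood at 53660 and 11110 CPM among nuclear counts (13190 to 42520 and 1487 to 6821 in the baseline). By list, oligodendrocyte (2.11), neuron (1.87) and astrocyte markers (1.39) were higher than the baseline (percentiles 99.85, 99.92 and 99.24).

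The library labelled healthy bone marrow-derived macrophage was set against the 3 macrophage baseline libraries likewise. Nos2 stood at 1.097 CPM against 531.0 ± 192.9 CPM and Timp1 at 0.0757 against 42.3 ± 26.3. Interferon-gamma genes had a median log2 ratio of -4.54 (19 of 20 below all 3), inflammatory cytokines of -4.16 (23 of 26), type I interferon genes of -2.92 (24 of 25) and MHC class II genes of -2.73 (11 of 14). Cell cycle genes lay above all 3 in 24 of 25 (4.62), as did 15 of 15 neutrophil markers and 5 of 5 erythroid markers. The antimicrobial peptide gene Camp stood at 1337 against 0.480 ± 0.628 CPM, Itgb2l at 296.1, Fcnb, a ficolin of granulocytes, at 204.5 and Serpinb1a at 152.2 CPM, beside S100a8 at 10230, S100a9 at 15270 and Ngp at 6722 CPM.

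The test of sex in this part was chosen after the result was seen. Xist, the RNA of the inactive X chromosome, stood at 877.4 to 3368 CPM in all 23 EAE libraries, where the Y-linked genes Ddx3y and Eif2s3y reached at most 0.0611 and 0.121 CPM. Kdm5d, also Y-linked, had 0 counts in all of them, but Uty stood at 0.627 to 2.93 CPM. In the healthy libraries Kdm5d had 11.6 and 6.19 and Uty 3.76 and 6.07 CPM. Xist stood at 54.9 CPM beside Ddx3y at 4.11 and Eif2s3y at 32.0 CPM in the healthy microglia library and at 584.2 beside 13.2 and 28.3 CPM in the healthy bone marrow-derived macrophage library. A candidate explanation is that EAE libraries came from female mice and healthy libraries hold cells of male mice or of both sexes. Uty keeps this open, since its EAE reads were not traced. The labels give no sex, and with it healthy and EAE libraries would differ in more than disease.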
